A study of Mus musculus with 4 samples.

How the data were processed

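Small RNAs co-purified with PIWIL1 from adult mouse testis were measured in 2 libraries, and testis RNA of Piwil1+/- and Piwil1-/- mice at postnatal day 23 in 1 library each. Per the labels' protocols, PIWIL1-bound RNA was size-selected on a gel and made into libraries with a NEBNext small RNA kit, and testis RNA was depleted of ribosomal RNA and made into directional TruSeq libraries. Samples were grouped by the titles and genotypes in the labels.

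The authors deposited the small RNA data as read counts: per the file headers, 1 row per distinct sequence with its count in each replicate. Every sequence is 50 nt long and still carries the 3′ adapter, and reads made of adapter alone are present. Per the submitters' processing notes, Bowtie, STAR and the mm10 genome build were used; the settings, the versions and the data type each tool was used for are not given in the sources used here. The small RNA table holds no alignment. The authors deposited the RNA-seq data as RPKM, reads scaled by gene length and by the library's mapped reads, per the file headers, for 22808 gene identifiers. The read counter, the annotation and any use of strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart.

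Inserts were taken as the bases before an exact match to AGATCGGAAG, the first 10 nt of the adapter seen in the reads, a step chosen after the reads were seen. The match left an insert of 1 nt or more in 97.6% of reads of replicate 1 and 98.7% of replicate 2. No match was found in 1.95% and 1.27%, and 0.409% and 0.0651% were adapter alone. These were left out. Inserts of the same sequence were summed, and shares are percentages of insert reads. Values are means ± SD over 2 libraries; exact (Clopper-Pearson) binomial intervals per library are given for the length class. Trimming by exact match misses reads with a sequencing error in the matched bases, and short inserts can include degradation products. Sequences are written with T as in the files, and U is used in the text.

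Gene symbols were taken from a table of gene names and matched 22444 of the 22808 identifiers, ignoring version suffixes. Coordinates are those of the RefSeq genes of GRCm38.p6, the assembly named mm10 in the processing notes. Log2 ratios are differences of log2 (RPKM + 1), Piwil1-/- minus Piwil1+/-, over genes with an RPKM of 1 or more in either library. With 1 library per genotype no count test or p-value was possible. Gene lists, fixed before the data were examined, cover germ cell stages, the piRNA pathway, CREM and ACT targets, testicular and other somatic cells, stress responses, ribosomal, mitochondrial and housekeeping genes. Each list's median was placed among 10000 random lists of the same size matched on mean log2 expression in 20 bins, as a description of these 2 libraries.

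RPKM values of a gene in the 2 libraries are whole read numbers divided by the same gene length and by each library's total. The ratio of the totals was read from low genes and the totals from 49 genes with a RefSeq span under 1500 bp, which gave 104014686 and 100254357 reads. Read numbers followed for 15324 of 16558 genes above 0 in both libraries, 92.5%. For genes at 0 in 1 library, the smallest whole reads and gene length that fit the other value were taken; those of Prm2 imply a gene far shorter than its RefSeq span and were not used. Read numbers are the smallest that fit, since a factor common to reads and gene length is lost, and are written as "at least". The counting interval of a fold comes from an exact binomial interval of these reads and covers counting error only; fewer reads in the same ratio widen it, while PCR copies make it too narrow by an unknown amount. Piwil1 had 2730 reads per kilobase in Piwil1+/-.

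The methods were tested on simulated data. For the genotype comparison, reads were drawn for the real genes at the real totals. Of 17615 genes above 0 in both simulated libraries, 85.8% got read numbers, 99.97% of these in the true ratio, and both totals were found exactly. Gene lengths were random there and known exactly. Finding the totals therefore does not test the use of RefSeq spans as gene lengths in the real data. Of 100 genes changed 4-fold, 98% passed the 2-fold rule, of 100 changed 3-fold 92%, and of 9543 unchanged genes 0 passed. These draws hold no difference between animals. Of 200 random lists of 17 genes, 4.0% fell outside the central 95%. Of 20000 simulated small RNA reads with base errors at 0.2%, 98.6% were given their true length. The pairing of small RNA starts, described with its result, gave 1.01 at 10 nt in 40000 simulated inserts without planted pairs and 1.27 with 200 planted pairs. Those inserts mostly started with U, held all bases evenly elsewhere and counted equally, unlike the real small RNAs. The 1.01 is therefore no estimate of the background in the real data.

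Genes named in the text are Piwil1, the 10 highest and 10 lowest log2 ratios among genes with a symbol, and up to 2 highest and 2 lowest members of each list; of the small RNAs, the 5 most abundant. Prm1, Prm2, Prm3, Tnp1, Tktl2 and the members of gene families named under other observations, such as Tex101, were added after their values were seen. Alternatives fixed before the data were examined were other pseudocounts, expression filters, centring, trimmed-mean rescaling and fold thresholds for RNA-seq, and distinct sequences, a read minimum, length classes and single replicates for small RNAs. No reference genome was used here, so the genomic sources of the small RNAs, their overlaps on the genome and the RNA change of the genes they come from were not analysed. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.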

Results

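The data came from mouse testis and covered 4 libraries. Small RNAs bound to PIWIL1, also called MIWI, a PIWI-clade Argonaute protein of meiotic and postmeiotic male germ cells, were sequenced from adult wild-type C57BL/6J animals of 10 weeks in 2 replicate immunoprecipitations. Testis RNA was sequenced in 1 library each of Piwil1+/- and Piwil1-/- mice at postnatal day 23. At that age the synchronous wave of spermatogenesis that starts after birth has filled the tubules with meiotic cells and is producing spermatids. The small RNA libraries held 4836797 and 6408274 reads for replicates 1 and 2. The RPKM values of the RNA-seq table were scaled to 104014686 reads in Piwil1+/- and 100254357 reads in Piwil1-/-. Counting intervals given below are 95% intervals that cover counting error only, because PCR copies of a molecule are not independent.

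The first question was what PIWIL1 carries in the adult testis. Its small RNAs formed a single narrow length class, the size range of pachytene PIWI-interacting RNAs (piRNAs). The commonest length was 30 nt, with 33.4% ± 2.05 of the trimmed reads (SD, n = 2), followed by 31 nt with 22.2% ± 1.32 and 29 nt with 18.7% ± 1.36. Together, small RNAs of 29 to 31 nt made up 74.3% ± 4.74 of the reads, with 71.0% in replicate 1 (exact binomial interval 70.9% to 71.0%) and 77.7% in replicate 2 (77.6% to 77.7%). Each length from 21 to 23 nt, the length of microRNAs, held at most 0.651% of the reads on average. Replicate 1 held more fragments under 15 nt than replicate 2, 4.19% against 0.456% of its reads. No control immunoprecipitation was analysed here, so these shares describe what was recovered with PIWIL1 and not an enrichment. The RNA was also size-selected on a gel, so the narrow length class and the few short reads may partly reflect that step.

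**Figure D1:**
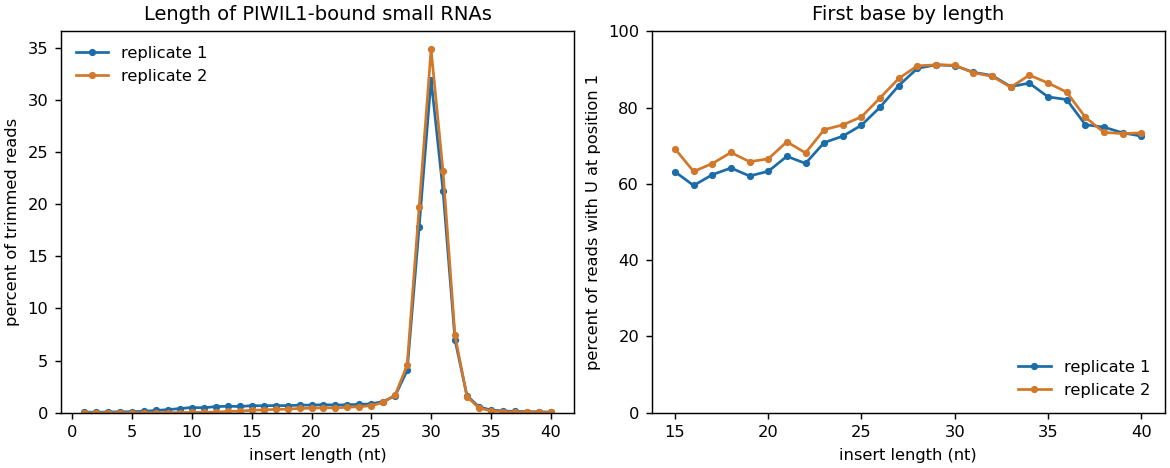
Left, percent of trimmed reads (vertical axis) at each insert length in nt (horizontal axis) in the 2 PIWIL1 immunoprecipitation libraries, 1 line per library. Right, percent of reads with U at position 1 by length from 15 nt; both libraries peak at 30 nt, and the U share at 29 nt averages 91.2% against 66.2% at 15 nt.

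PIWIL1-bound small RNAs began with U in 87.9% ± 1.62 of all reads (n = 2) and in 90.1% ± 0.0924 of reads of 26 to 33 nt, the range used for base composition. Averaged over positions 11 to 24 of the same reads, the U share was 30.7% ± 0.0478. Reads of 15 to 23 nt began with U less often, at 66.4% ± 2.88. Adenine at position 10, the mark of piRNAs made by the ping-pong cycle, in which a piRNA-guided cut sets the 5′ end of a piRNA from the opposite strand, was found in 30.5% ± 0.0787 of reads. Its share was 24.9% ± 0.273 at position 9 and 26.6% ± 0.440 at position 11. The difference between position 10 and each neighbour was larger than the spread between replicates, but adenine was not highest at position 10: in reads of 26 to 33 nt it made up 32.8% ± 0.277 at position 4 and 33.03% ± 0.159 at position 6, against 30.7% ± 0.205 at position 10. Among reads of 26 to 33 nt, the share with A at position 10 was 41.7% ± 0.0859 in those not starting with U and 29.5% ± 0.206 in those starting with U.

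Beyond the first base, the strongest composition was at positions 2 and 5. Adenine made up 41.2% ± 0.563 of bases at position 2 and 46.2% ± 0.0313 at position 5, against a mean of 27.4% ± 0.213 over positions 11 to 24. Guanine was at 8.56% ± 0.137 at position 5, against 21.4% ± 0.278 over positions 11 to 24. With each 5′ end counted once, taken as the first 20 nt, position 5 held 39.5% ± 0.0637 adenine and 12.02% ± 0.0449 guanine. Small RNAs that did not start with U also had little guanine at position 5, at 10.9% ± 0.252. These differences were seen in both libraries and were larger than the spread between them.

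**Figure D2:**
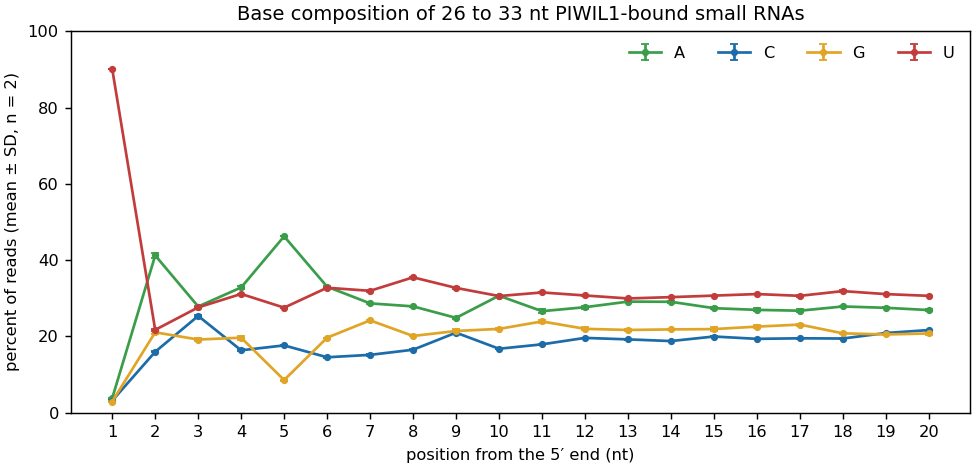
Percent of 26 to 33 nt reads (vertical axis) with each base at positions 1 to 20 from the 5′ end (horizontal axis). Points are means and bars SDs of the 2 PIWIL1 immunoprecipitation libraries; U reaches 90.1% at position 1, and at position 5 A reaches 46.2% while G drops to 8.56%.

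The 5′ ends of the PIWIL1-bound small RNAs were sharper than their 3′ ends. Among 5′ ends with 100 or more reads, a median of 47.0% ± 0.0438 of reads shared the commonest 3′ end. Among 3′ ends with 100 or more reads, a median of 93.3% ± 0.0223 shared the commonest 5′ end. The population was diverse but uneven: of 484174 and 580882 distinct 5′ ends in replicates 1 and 2, 5447 and 4806 held 50% of the reads of 26 to 33 nt. The most abundant small RNA averaged over both libraries was the 31-nt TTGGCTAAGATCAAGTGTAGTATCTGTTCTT, at 2748 ± 1041 reads per 1000000 insert reads (n = 2). It was followed by the 29-nt TTTGAAATCAGGACTGTTCTGGAAATTCC at 1734 ± 398, the 32-nt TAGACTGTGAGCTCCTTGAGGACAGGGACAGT at 1711 ± 230, the 29-nt TAGGAACTATTGGTGTTCTTTAGACGACC at 1537 ± 9.35 and the 31-nt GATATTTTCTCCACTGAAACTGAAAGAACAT at 1514 ± 168 reads on the same scale. The fifth is the exception among them in starting with G. Their genomic positions were not determined here.

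Both immunoprecipitations recovered largely the same abundant small RNAs. Of 2517272 distinct small RNAs, 488925 were seen in both libraries, and these carried 76.8% of the reads of replicate 1 and 80.4% of those of replicate 2. Across sequences, which are not independent replicates, Pearson's r of log2 (reads per 1000000 insert reads + 1) was 0.799. Spearman's rho was -0.20 across all sequences, most of which were seen in a single library, and 0.69 across those seen in both. For 12804 small RNAs of 26 to 33 nt with 100 or more reads in total, 97.2% differed by less than 2-fold between the libraries. The mean chi-square per sequence was 5.82, where read sampling alone gives 1. The libraries were counted as 2 replicates because the labels call them so, and the labels do not say whether they came from separate animals.

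The RNA-seq libraries addressed what happens to testis RNA when PIWIL1 is missing. Piwil1 itself (chromosome 5, 128736071 to 128755474, mm10) was at 26.2 RPKM in Piwil1+/- testis and was listed at 0 in Piwil1-/- testis, matching the labels. With 1 library per genotype no difference below has a replicate check and no p-value is given. The 2-fold rule was applied to log2 (RPKM + 1), a scale that understates the change of low genes, and to the 9951 genes with an RPKM of 1 or more in either library.

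Most RNAs were at similar levels in the 2 genotypes, and the differences were mainly on the lower side. In Piwil1-/- testis 195 genes were at least 2-fold lower and 23 at least 2-fold higher, while 9733 genes, 97.8%, lay within 2-fold. The median log2 ratio of all these genes was 0.0055 and Pearson's r across genes was 0.979. The counting interval of the fold, from the smallest read numbers that fit the RPKM values, excluded 1 for 192 of the lower and 19 of the higher genes. The values did not fix usable read numbers for Piwil1, Akap4 and Prm2 among the lower genes, nor for Ptchd3, Tdrd1, Tex101 and Tktl2 among the higher. With a pseudocount of 0.1 RPKM the counts were 332 lower and 68 higher.

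**Figure D3:**
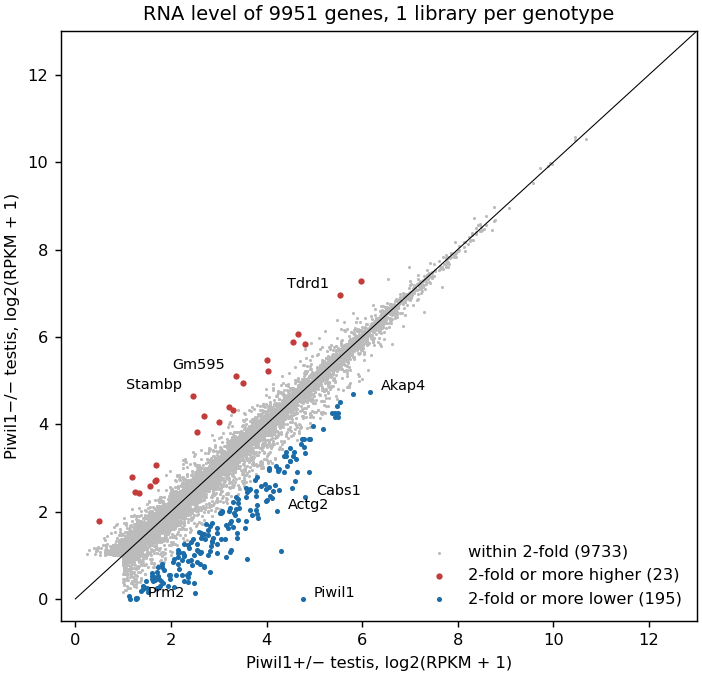
RNA level as log2 (RPKM + 1) in Piwil1+/- (horizontal axis) and Piwil1-/- testis (vertical axis), 1 point per gene and 1 library per genotype, with the line of equal level. Blue points are the 195 genes at least 2-fold lower and red points the 23 at least 2-fold higher in Piwil1-/-; Piwil1 sits at 0 on the vertical axis.

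After Piwil1, the lowest ratios included genes of late male germ cells. The lowest was 4930503B20Rik (chromosome 3, 146645189 to 146685892), at 18.8 RPKM in Piwil1+/- and 1.15 in Piwil1-/-, a ratio of 0.0613 (interval 0.0457 to 0.0807) from at least 914 and 54 reads. Usp50, of the ubiquitin-specific protease family, had a log2 ratio of -2.68. Cabs1, a calcium-binding protein of spermatids and sperm, went from 27.03 RPKM in Piwil1+/- to 4.05 in Piwil1-/- (log2 ratio -2.47). Spem1, required for sperm to shed their cytoplasm, had a log2 ratio of -2.21 and Rnf148, a RING finger protein gene, one of -2.20. Gm136, Fam71a and Wdr64 had log2 ratios of -2.37, -2.16 and -2.15. Actg2 (chromosome 6, 83512909 to 83536251) encodes the smooth muscle gamma actin. It was at 17.6 RPKM in Piwil1+/- and 3.04 in Piwil1-/- (log2 ratio -2.20), and the cells its RNA came from were not determined.

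The highest ratio belonged to Stambp (chromosome 6, 83543206 to 83575826), which encodes an endosomal deubiquitinating enzyme and lies 6955 bp from Actg2. It was at 4.47 RPKM in Piwil1+/- and 24.01 in Piwil1-/- testis, 5.37-fold higher (interval 4.92 to 5.87) from at least 593 and 3069 reads. The uncharacterised gene Gm595 was at 9.27 and 33.5 RPKM, and Ceacam20, of the carcinoembryonic antigen-related adhesion family, at 1.29 and 5.88. Prelid1, a mitochondrial phospholipid transfer protein, had a fold of 3.15 (2.80 to 3.55), and Mtif2, a mitochondrial translation initiation factor, one of 2.60 (2.44 to 2.76). Man2a2, a Golgi alpha-mannosidase, was 2.86-fold higher (2.80 to 2.93) and Zfp184, a zinc finger gene, 2.89-fold higher (2.73 to 3.07). Ptchd3 and Lrrc61 had log2 ratios of 1.42 and 1.39. Tdrd1, a tudor domain protein of the piRNA pathway (chromosome 19, 56826171 to 56870012), was at 45.7 RPKM in Piwil1+/- and 123 in Piwil1-/-.

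Genes of elongating spermatids were lower in Piwil1-/- testis. Of 17 members measured, 12 were at least 2-fold lower in Piwil1-/- and none was at least 2-fold higher; the median log2 ratio was -1.28, below the medians of all 10000 random lists matched on expression. Besides Cabs1, Fscn3, a testis fascin, was at 4.04 and 0.453 RPKM. Akap4, the main anchoring protein of the sperm tail fibrous sheath, was at 70.5 and 25.8 RPKM, and Tnp2, a transition nuclear protein, at 2.25 and 0.197. The list also held members near the line of equal level: Tekt4, a sperm flagellar tektin (log2 ratio -0.31), and Tuba3b, a testis alpha-tubulin (0.04). Prm2, a protamine gene, was at 1.42 RPKM in Piwil1+/- and listed at 0 in Piwil1-/-. Prm1, Prm3 and Tnp1, the list members not measured, were under an RPKM of 1 in both libraries. With these genes at or near the floor, the list cannot show whether elongating cells were present in either testis. Without the members shared with the CREM and ACT targets, Prm2 among them, the median of the remaining 10 genes was -1.24.

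Genes of round spermatids were also lower, by less. Their median log2 ratio over 23 genes was -0.56, again below all 10000 random lists, with 5 genes at least 2-fold lower and 21 below 0. Spert, a spermatid-associated protein, was at 8.43 and 2.34 RPKM and Fhl5, the CREM coactivator ACT, at 21.6 and 7.86. Dpy19l2 and Spata16, both needed for the acrosome, had log2 ratios of 0.03 and 0.05. Targets of the transcription factor CREM and its coactivator ACT had a median of -1.21 over 14 genes, below all random lists, with 9 at least 2-fold lower. Of its measured genes, 7 are also in the elongating and 4 in the round spermatid list and 1 in the late pachytene list, so these lists are not independent; the 2 CREM and ACT targets in no other list had a median of -0.73. Its members nearest 0 were Acr, the acrosomal protease acrosin (-0.09), and Ldhc, the testis lactate dehydrogenase (-0.15).

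Genes of earlier germ cells showed no such difference. Meiotic prophase genes had a median log2 ratio of 0.10 over 23 genes, at the 99.75th percentile of random lists, with none past 2-fold; Meioc, needed for meiotic entry and prophase, was at 0.23, Mei1 at 0.27, Rec8, the meiotic cohesin, at -0.20 and Syce2, of the synaptonemal complex, at -0.23. Late pachytene and meiotic division genes had a median of -0.07 over 17 genes (percentile 4.85). There, Hspa1l, a testis HSP70, was at 7.23 and 1.58 RPKM, while Nme5 had a log2 ratio of -0.31 and Ybx2, an RNA-binding protein of germ cells, one of 0.43. Spermatogonial genes had a median of 0.04 over 7 genes (percentile 64.3), with Uchl1 at -0.08 and Stra8 at 0.09.

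Other genes of the piRNA pathway were, Tdrd1 apart, within 2-fold. The median log2 ratio of 21 genes was 0.06 (percentile 93.2) and 17 of them lay above 0. Tdrd12, a tudor domain helicase, was at 43.6 and 62.0 RPKM, and Gtsf1, a PIWI cofactor, at 59.5 and 48.8. Btbd18, a transcriptional activator of pachytene piRNA genes, had a log2 ratio of -0.06.

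Genes of the testis's somatic cells differed little, and not all in 1 direction. Sertoli cell genes had a median of 0.10 over 12 genes (percentile 95.4), with Trf, transferrin, at 0.46 and Gata1 at -0.17. Leydig cell genes had a median of -0.14 over 10 genes (percentile 1.51), with the steroidogenic enzymes Cyp11a1 and Cyp17a1 both at -0.31. Peritubular and smooth muscle genes had a median of 0.02 (percentile 56.2) but a mean of -0.25, since Actg2 was far below the other 7; Acta2, the alpha actin of peritubular myoid cells, was at 0.14. Leukocyte and endothelial genes had medians of 0.08 over 6 genes (percentile 77.9) and -0.02 over 3 genes (38.1). Red blood cell genes had a median of -0.41 over 3 genes (percentile 2.02), led by Hbb-bs at -0.60. Of the epididymal genes, 2 were measured: Cst8, which is also expressed in testis, was at 12.9 and 2.86 RPKM, and Rnase10 at 1.83 and 1.01.

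No stress or housekeeping list had a median outside the central 95% of its random lists. The p53 and apoptosis genes had a median of 0.10 over 7 genes (percentile 86.6), with Aen, a p53-induced nuclease, highest at 0.85. Unfolded protein response genes had a median of -0.02 and a mean of 0.01 over 10 genes (percentile 34.9), with Sdf2l1 at 0.50 and Ddit3 at -0.21. Interferon response genes had a median of -0.12 over 3 genes (percentile 15.9). Ribosomal protein genes had a median of 0.01 over 24 genes (63.7), which passed below 0 after trimmed-mean rescaling, mitochondrially encoded genes one of -0.11 over 8 genes (4.31) and housekeeping genes one of 0.03 over 12 genes (74.5). No immediate early gene reached an RPKM of 1 in either library. In all, 6 of 19 lists lay outside the central 95%, and 3 of these are the spermatid and CREM lists. Lists of genes drawn at random would give about 0.95. Members of a real list may vary together between 2 libraries, and some lists share members, so this number is no test.

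**Figure D4:**
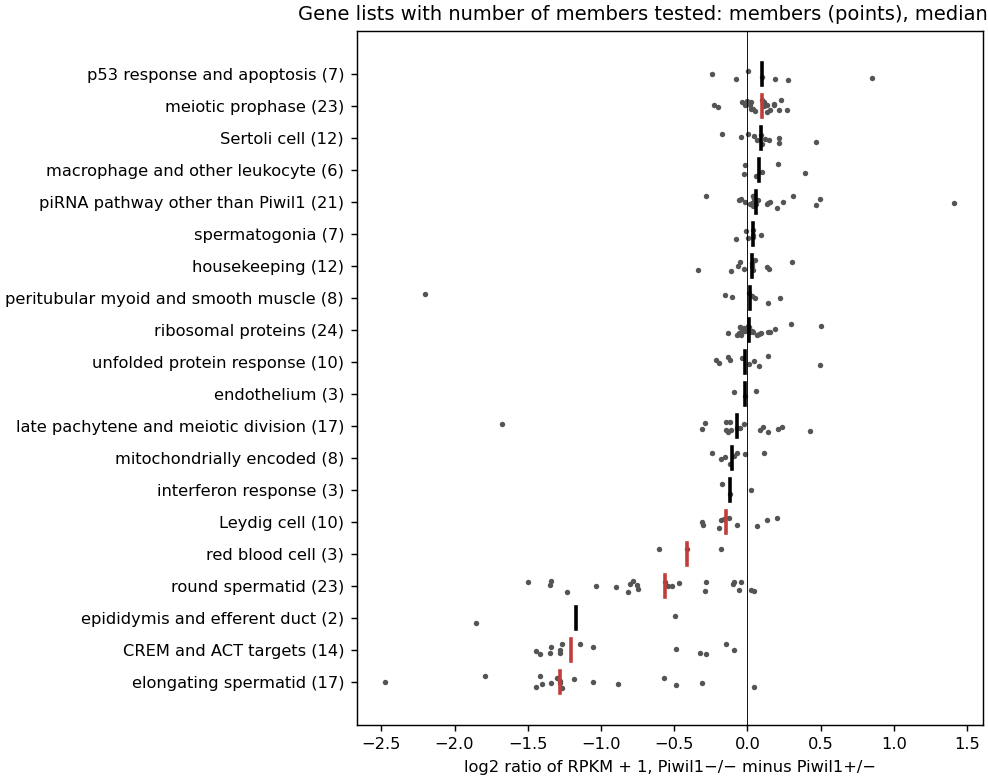
Log2 ratio of RPKM + 1, Piwil1-/- minus Piwil1+/- testis (horizontal axis), for the measured members of each gene list (points, spread vertically for visibility) and the list median (bar), with the number of members in parentheses. Red bars mark the 6 lists whose median lies outside the central 95% of matched random lists; the elongating spermatid median is -1.28 and the meiotic prophase median 0.10.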

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

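The tests in this part were chosen after the results were seen, except that on starts read backwards and weighted by reads, whose outcome had not been seen.

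Inserts of 15 to 23 nt, outside the piRNA length class, made up 6.45% of the reads of replicate 1 and 3.49% of replicate 2, and drew attention as a signal in data that the main comparisons do not use. In 73.4% ± 2.64 of these reads (n = 2) the first 15 nt also start an insert of 26 to 33 nt, and in 21.6% ± 2.48 they lie only inside such an insert.

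The pattern most open to follow-up is that spermatid genes were lower in Piwil1-/- testis. Library scaling is argued against, because 1 factor would move all lists alike and the 95% interval of the housekeeping median began 0.82 above the end of that of the elongating spermatids on the log2 scale. A larger share of somatic cells is argued against too, since the interval of the meiotic prophase median began at 0.0165, well above that of the elongating spermatids, and somatic lists did not move together. A Piwil1-/- testis that was at an earlier point of the postnatal wave for reasons apart from its genotype cannot be told apart from an effect of the genotype with 1 library each. It would also leave later genes lower than earlier ones, as seen, with the round spermatid median 0.71 above the elongating one on the log2 scale.

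For the 23 genes at least 2-fold higher, led by Stambp, a relative gain of meiotic prophase cells as a whole is argued against. The interval of the meiotic prophase median ended at 0.13 on the log2 scale. That interval covers the median of a list, so a gain of a narrower stage that the list does not mark was not tested. Foreign DNA beside the targeted Piwil1 gene is argued against by position: 0 of the 21 higher genes with coordinates lie within 20 Mb of Piwil1. Counting error is argued against for the 19 genes with read numbers, whose lowest interval bound for the fold was 2.03. A difference between the animals of the 2 libraries that has nothing to do with Piwil1 stays open for each of these genes, as does the genotype.

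A further pattern concerns small RNAs whose 5′ ends pair: without a genome, an overlap of 10 to 26 nt on opposite strands was read from 10 matching bases and divided by the number a first-order model of the starts gives. The ratio at 10 nt was 4.16 ± 0.0390 (n = 2), against a mean of 1.16 and a highest of 1.69 at 11 to 26 nt. A few abundant small RNAs carry much of it. Each pair of 10-nt starts was weighted by the product of its 2 read counts. On that weight, 5 and 4 pairs held 50% of the total in replicates 1 and 2. That is not 50% of the reads with a partner. With each distinct sequence of the first 26 nt counted once the ratio was 1.41 ± 0.0214, against a mean of 1.21 at 11 to 26 nt. It lay above the highest other overlap by at least 0.138 in each library. Variants of an abundant small RNA that share its first 10 nt still count separately there. This count therefore cannot show how much of the excess comes from abundant small RNAs. By reads, starts read backwards without complementing gave 1.12, against 4.16 at 10 nt. The 1.12 lay below the mean of 1.16 at 11 to 26 nt, so it may understate the background of complementary matches. It argues only against a base composition that raises backwards and complementary matches alike. With each distinct first 26 nt counted once, the backwards ratio lay below the ratio at 10 nt by at least 0.275 in each library, more than the spread between libraries. That backwards ratio, 1.12, was also below the mean of 1.21 at 11 to 26 nt. It understates the background of complementary matches there, so the 0.275 cannot be read as the excess over background. Ping-pong pairing may be the source, a hypothesis for which the design holds no group to test, and complementary small RNAs from repeats were not tested without a genome.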

How the results depend on the processing

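The adapter match, the 26 to 33 nt and 5′ end correlations, the pairing of starts and the lists without shared members were chosen after seeing the data. The share of 29 to 31 nt was 57.2% with distinct sequences counted once and 84.5% with sequences of 10 or more reads, and ranged from 71.0% to 77.7% over single replicates. The share starting with U was 80.1% and 91.7% under the same 2 settings, 90.5% in reads of 29 to 31 nt, and 86.8% to 89.1% over single replicates. The share with A at position 10 was 29.1% and 31.4%, then 30.8% in reads of 29 to 31 nt and 29.7% in those of 26 to 28 nt, and 30.4% to 30.5% over single replicates. Matching 6 or 12 nt of the adapter left all 3 within 1 SD. Pearson's r was 0.912 over sequences seen in both libraries, 0.856 with 10 or more reads in either, 0.270 with a pseudocount of 0.1, 0.839 at 26 to 33 nt and 0.914 over 5′ ends. Spearman's rho changed sign, to 0.69, 0.73 and, over 5′ ends, 0.0902, because sequences seen in a single library left the set or were merged.

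Genes at least 2-fold higher and lower numbered 68 and 332 with a pseudocount of 0.1, 39 and 253 with 0.5, 20 and 126 at an RPKM of 5 or more, 141 and 518 at 1.5-fold, and 1 and 11 at 4-fold; the same 23 and 195 genes passed under both pseudocounts, centring and rescaling, the last 2 of which added 4 lower genes each. The Piwil1 log2 ratio was -8.04 with a pseudocount of 0.1. Of 123 list medians under alternatives 117 were counted as within their interval or, for the 2 epididymal genes, which have none, within 0.1. The lists outside the central 95% kept their sign. The other 6 were endothelium at -0.0936 and epididymis at -1.85 (RPKM of 5 or more), epididymis at -1.47 and interferon at -0.20 (pseudocount of 0.1), and epididymis at -1.31 (0.5) and 0 (no filter). The endothelium value equals the lower end of its interval to the digits kept, so it lies at the limit and not past it. The cause of these moves was not tested. The p53, unfolded protein, interferon, ribosomal and housekeeping medians crossed 0 under some settings, within their intervals. Of 516 values of named genes under alternatives 487 stayed the same within their counting interval, or 0.1 where none was given, and 0 of those past 2-fold changed sign. No paired analysis was possible because each genotype had 1 library and the small RNA libraries form a single group. Alternatives for genomic overlaps, genomic sources and source genes were not run, as no genome was used here. Depth limits single small RNAs, most of which were seen in 1 library.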

Other observations

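The groups in this part were chosen after their values were seen. All 30 members of the X-linked Btbd35f family with reads, a multicopy cluster of BTB domain genes, were higher in Piwil1-/- than in Piwil1+/- testis, although 7 of them passed the RPKM minimum and none the 2-fold rule. Their summed level was 6.60 RPKM in Piwil1+/- and 18.3 in Piwil1-/-, 2.78-fold higher, where the highest of 10000 random sets matched on level gave 1.37. Reads of such similar copies cannot be assigned with certainty, so these are not 30 independent measurements. The 33 measured genes of chromosome Y, many of them also multicopy, had a median log2 ratio of 0.18, above all matched random lists, with Gm20852 highest at 0.54 and Gm20777 lowest at -0.82. The 250 measured Zfp zinc finger genes had a median of 0.06, above all random lists, and 162 of them lay above 0.

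Families of testis and sperm genes went in different directions. The 25 measured Spata genes, named for spermatogenesis, had a median of -0.67, below all random lists, with Spata31d1b lowest at -1.67 and Spata4 highest at 0.09. Adam genes, which include sperm surface proteases, had a median of -0.14 over 25 genes (percentile 0.06), and Tex genes one of -0.17 over 32 genes, though Tex101, a germ cell surface protein, was at 1.29. The 12 axonemal dynein heavy chain genes (Dnah) had a median of 0.17 (percentile 99.97), while the 28 Cfap genes of cilia and flagella stood at -0.02 (percentile 27.2) and the 20 Prss proteases at -0.07 (percentile 5.29).

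Stambp and Actg2, with the highest ratio of all and one of the 10 lowest, are neighbours on chromosome 6. They were the single case in which a gene at least 2-fold higher had a gene at least 2-fold lower within 50 kb. This was among 21 higher genes with coordinates. Of 10000 matched random sets, 42.0% held as many such cases, with a mean of 0.539. That comparison counted cases only. It used neither the size of the 2 ratios nor the distance within 50 kb, so it cannot show how unusual this pair is.

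Of reads of 26 to 33 nt, 0.936% ± 0.00522 (n = 2) had first 20 nt whose reverse complement lay in another small RNA of these libraries.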
